A study of Mus musculus with 20 samples.

How the data were processed

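Total RNA from the left ventricle of C57Bl/6 mice was measured on 20 single-colour microarrays, 4 in each of 5 groups. Per the labels' protocols, RNA was purified on columns, copied into double-stranded cDNA and labelled with Cy3. Per the labels, the arrays were of a NimbleGen 12-array format on the MM9 mouse build. Per the submitters' processing notes, the values were made with RMA, a method that in its usual form corrects background, normalises arrays against each other and summarises the probes of a feature. Its version, and which of these steps were run over which arrays, are not given in the sources used here. The deposited values are RMA intensity values on a linear scale, 1 per feature and array, per the file headers and the range of the values.

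The files held 44170 features, almost all of 3 probes, and 1 control feature of 5000 random probes that was left out of all tests. The submitters' value table held the same intensities as the files of the single arrays: 0 values differed by over 0.001. The median intensity per array was 281 to 320, and the random-probe control read 18.2 to 26.4. No count of molecules lies behind an intensity, so the number of arrays limits the precision. The labels do not say that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. No 2 arrays held identical values.

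Intensities were turned into log2 values. Features given the same gene symbol in the files were averaged on that scale, and the 2284 features without a symbol were kept as genes of their own, which left 26487 genes. Of 24203 symbols, 21583 were matched through the Entrez identifier to a RefSeq gene table of the assembly GRCm38.p6, which was used for names and gene types only, and 3258 were updated. Several features were averaged for 10194 genes. Coordinates are those of the files, on MM9. A pseudogene is a gene that this table gives as one, and pseudogenes may share sequence with their parent genes, so their values are uncertain.

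Each gene was tested in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes), with group means over all 20 arrays and no covariate. Residual degrees of freedom were 15 per gene, with a prior of 2.98. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Comparisons were MDMA against saline at 10 days, MDMA against saline at 35 days, 10 days of MDMA followed by 25 days of saline against saline at 35 days, both MDMA groups of the 35-day arm against each other, and the difference between the MDMA effects at 35 and at 10 days. Unless stated otherwise, every adjusted p for a gene is limma's. The 10-day groups lay on 1 slide and the 35-day groups on another, so every comparison of single groups lies within a slide. The difference between the MDMA effects sets 1 slide against the other, and duration cannot be told apart from slide. On the second slide each group held its own block of 4 array positions, so position and group cannot be told apart there.

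Sets were 37 gene lists of clock genes, stress, metabolic and signalling pathways, and markers of the cell types that a ventricular sample could hold. Each list was tested with limma's camera at a preset correlation of 0.01 and adjusted over the 37 lists of a comparison. The same lists were tested with an estimated correlation and with fry. Members were also adjusted over the list alone. Differences between mean levels of a list were tested by exact two-sided permutation of the arrays, for which the smallest possible p with 4 against 4 is 0.0286. These permutation tests were added after the data had been seen.

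Genes to be named were set by rule: among called genes with no overlap between groups, a mean above the median of all genes in at least 1 group and a symbol that is neither provisional nor an olfactory or vomeronasal receptor, the 8 largest rises and the 8 largest falls; all members of the core clock lists, in comparisons against saline; up to 4 members of each list described; and, where fewer than 5 genes passed, the 4 genes of smallest p in each direction. Some genes that the rule names are not given here. Genes named outside that rule are given as chosen after their values were seen. Groups, tests, lists, this rule and the first set of alternatives were fixed before the data were examined.

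The first set held a replicate block, 3 other normalisations, the submitters' value table, leaving out dim features, 1 test per feature, only the arrays of the groups compared, odd or even array position, another variance model, array weights, another threshold and leaving out each array in turn. A sex signal, atrial and brown adipocyte covariates, leaving out arrays of deviating atrial signal and leaving out pseudogenes were added after the data had been seen. Other splits of the same arrays were counted, up to 100 per comparison. The steps were tested on simulated data: among 50 simulated genes per size, changed genes were recovered at 14%, 50%, 96% and 100% for log2 changes of 0.5, 1, 2 and 3 in the 10-day contrast, and at 6%, 54%, 90% and 96% in the 35-day one. Between 4 and 7 unchanged genes were called per comparison. The simulated noise was independent between genes, so these rates leave out shifts that many genes of an array share. No array was left out of the main tests.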

Results

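Gene expression was measured in the left ventricle of C57Bl/6 mice given MDMA (ecstasy, an amphetamine derivative that releases monoamines) or saline. The title of the series names cardiac gene expression, DNA methylation and circadian rhythm as its subjects, and only expression was analysed here. There were 5 groups of 4 arrays: saline for 10 days (Saline-10D), MDMA for 10 days (MDMA-10D), saline for 35 days (Saline-35D), MDMA for 35 days (MDMA-35D), and MDMA for 10 days followed by saline for 25 days (MDMA-10/25D). The median intensity was 281 to 320 per array, and the random-probe control read 18.2 to 26.4, so that most genes lay well above it. In the text, changes are log2 differences between group means ± SE with n = 4 arrays per group.

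Markers of tissue around the ventricle differed widely between arrays. Myl7, the atrial myosin light chain, had log2 levels of 14.3 and 14.7 in Saline-10D replicates 1 and 3, of 6.54 and 7.88 in replicates 2 and 4, of 5.55 to 6.50 in the MDMA-10D arrays and of 12.4 to 14.9 in the 35-day arrays. Upk3b, a gene of the epicardial surface, averaged 9.28 ± 2.93 (SD, n = 4) in Saline-10D and 4.99 ± 0.267 in MDMA-10D. Ucp1, the uncoupling protein of brown fat, averaged 6.43 ± 2.37 and 5.42 ± 0.302 in these groups, and 12.0 ± 1.34, 11.3 ± 2.37 and 13.5 ± 0.968 in Saline-35D, MDMA-35D and MDMA-10/25D. Xist, which is expressed from the inactive X chromosome of females, was above a log2 level of 11 in 2 arrays of every group and below 6 in the other 2.

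**Figure D1:**
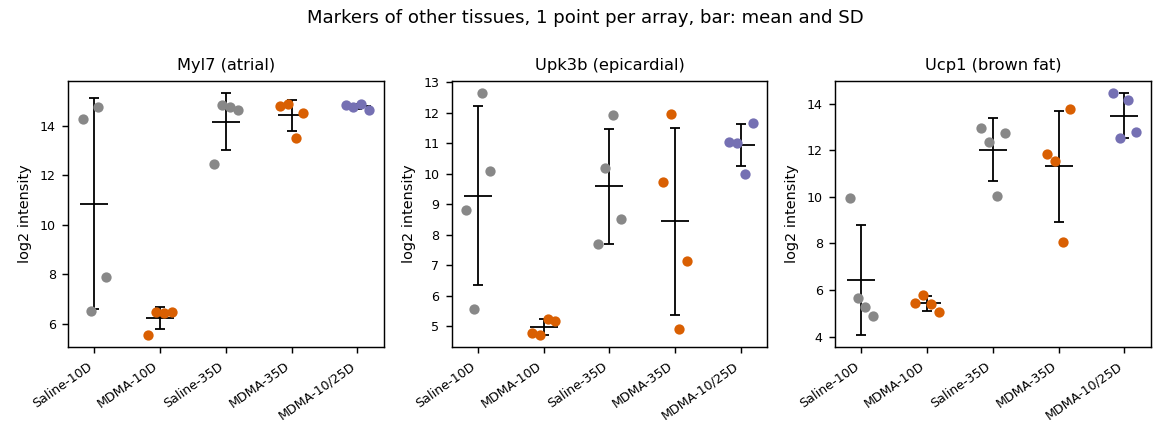
Log2 intensity (vertical axes) of Myl7, Upk3b and Ucp1 in the 5 groups (horizontal axes), with 1 point per array and bars for the mean and SD of 4 arrays. Myl7 lay at 5.55 to 6.50 in MDMA-10D and in Saline-10D either near 14 or below 8.

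The first comparison asked what 10 days of MDMA did to ventricular expression. Arntl, which encodes the clock activator BMAL1, was lower by a log2 change of −1.79 ± 0.32 in MDMA-10D than in Saline-10D, and its partner Npas2 by −1.22 ± 0.26. Clock repressors and output genes lay in the opposite direction: Per3 at +1.63 ± 0.30, Cry2 at +1.49 ± 0.48, Ciart at +1.21 ± 0.24, and Dbp, a transcription factor driven by the clock, at +0.86 ± 0.22. For Arntl, Npas2, Per3 and Ciart all 4 MDMA arrays lay beyond all 4 saline arrays. None of these genes passed over all genes (adjusted p = 0.185 for each). Adjusted over the list alone, Arntl and Npas2 of the 6 measured genes of the activator side fell, and Per3, Cry2, Ciart and Dbp of the 11 measured genes of the repressor and output side rose. The list named the activator side here also holds Cry1 and Nfil3, which encode repressors, so its mean does not describe activators alone.

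As lists, the activator side was lower in MDMA-10D (5 of 6 members lower, mean log2 change −0.55, camera adjusted p = 0.0176) and the repressor side higher (8 of 11 members higher, mean +0.51, adjusted p = 0.00930). Both calls were lost at adjusted p = 0.429 with an estimated correlation. The 4 MDMA arrays lay on 1 side of the 4 saline arrays in the mean of either list (exact permutation p = 0.0286 each, the smallest possible). The call of the repressor list was also lost without MDMA-10D replicate 4 (adjusted p = 0.0541). Clock averaged −0.12 ± 0.18 over 4 features that went apart, at −1.85, −0.59, +0.24 and +1.72, of which none passed, so that its mean did not describe them. Features also went apart in Nr1d2 (−0.98 and +0.15), Tef (−0.39 to +0.68) and Hlf (−0.60 to +0.25). The means of further members were Cry1 −0.02 ± 0.18, Nfil3 +0.01 ± 0.17, Per1 +0.57 ± 0.27, Per2 +0.30 ± 0.33, Nr1d1 −0.19 ± 0.16, Nr1d2 −0.41 ± 0.26, Bhlhe40 +0.12 ± 0.13, Tef +0.29 ± 0.19 and Hlf −0.30 ± 0.29. The cold-inducible genes Cirbp and Rbm3 differed by −0.06 ± 0.13 and +0.09 ± 0.19. Among 12 clock output genes described in heart, 9 were lower (adjusted p = 0.00425, and adjusted p = 0.429 with an estimated correlation). Adjusted over the list alone 5 of them fell and 1 rose, among them Slc41a3, which encodes a magnesium transporter (−0.51 ± 0.13), Leo1 (−1.64 ± 0.41), and Pdk4, an inhibitor of glucose oxidation (−0.47 ± 0.15).

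**Figure D2:**
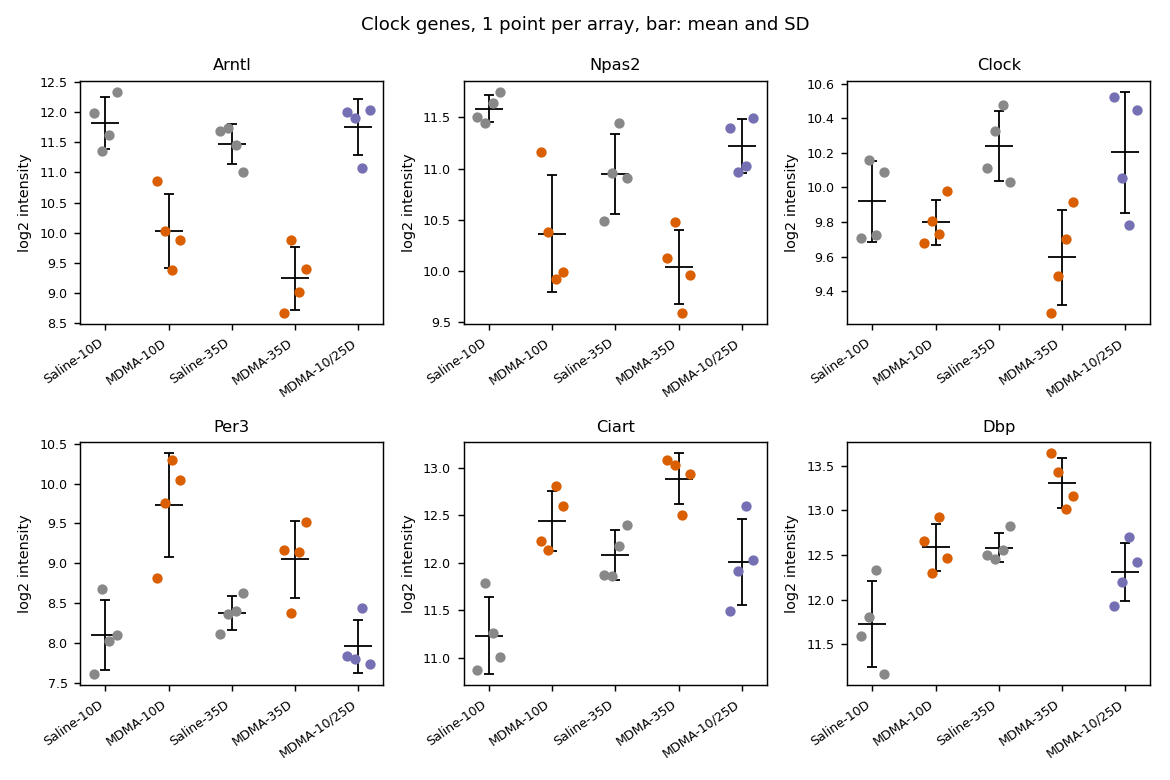
Log2 intensity (vertical axes) of 6 clock genes in the 5 groups (horizontal axes), with 1 point per array and bars for the mean and SD of 4 arrays. Arntl averaged 11.8 and 11.5 in the saline groups, 10.0 and 9.24 in the groups still on MDMA, and 11.8 in MDMA-10/25D.

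Genes of fuel use and of protein synthesis lay apart in MDMA-10D. Of 24 genes of fatty acid oxidation 20 were lower (mean −0.20, adjusted p = 0.00398), such as Acot2, a mitochondrial thioesterase (−0.79 ± 0.27) and Cpt1b, which carries fatty acids into muscle mitochondria (−0.27 ± 0.10). Of 42 ribosomal protein genes 36 were higher (mean +0.16, adjusted p = 0.00216), such as Rpl10a (+0.85 ± 0.28) and Rps13 (+0.65 ± 0.22). Both calls were lost at adjusted p = 0.459 with an estimated correlation, and 0 members passed in either list, over all genes or adjusted over the list alone.

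Ion channel genes were lower in 13 of 18 cases (adjusted p = 0.0125, and adjusted p = 0.429 with an estimated correlation). Kcnj5, which encodes a channel of the atrial acetylcholine-gated current, fell adjusted over the list alone (−2.20 ± 0.59), while Kcnip2, a subunit of the transient outward current, stood at −0.72 ± 0.27, and Kcnh2, the hERG channel, at −0.55 ± 0.20. The atrial markers stood beside this, with Myl7 at −4.61 ± 1.30 and Sln, a regulator of the atrial calcium pump, at −4.15 ± 1.38 (8 of 9 members lower, adjusted p = 0.00425, and adjusted p = 0.459 with an estimated correlation). All 7 epicardial markers were lower too, among them Upk3b at −4.29 ± 1.36 and Msln at −2.15 ± 0.75 (adjusted p = 0.00119, and adjusted p = 0.429 with an estimated correlation). Adjusted over the list alone, 2 atrial and 5 epicardial markers fell. Without Saline-10D replicate 3 the atrial call was lost (adjusted p = 0.133), and without MDMA-10D replicate 2 the ion channel call was lost (adjusted p = 0.0600).

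Further lists were lower in MDMA-10D: neutrophil markers (10 of 12 lower; Mmp9 −1.18 ± 0.40, Mmp8 −1.71 ± 0.62; adjusted p = 0.00462), fibroblast markers (10 of 12; Pdgfra −1.16 ± 0.33; 0.0176), monoamine genes (12 of 15; Maob, a monoamine oxidase, −1.03 ± 0.25; 0.0251), genes of the unfolded protein response (10 of 14; 0.0299) and genes of ubiquitin-dependent atrophy (12 of 14; Fbxo32 −0.51 ± 0.17, Ulk1 −0.61 ± 0.20; 0.0404). In the unfolded protein list the chaperones Hyou1 (−1.29 ± 0.33) and Hspa5 (−0.38 ± 0.11) fell and Ddit3, a transcription factor induced by stress, rose (+0.46 ± 0.16), adjusted over the list alone. Erythroid markers were higher in 10 of 10 cases (Bpgm +0.63 ± 0.21, adjusted p = 0.0176) and cell cycle genes in 13 of 15 (Birc5 +1.19 ± 0.56, adjusted p = 0.0404). With an estimated correlation the adjusted p was 0.429 for the neutrophil list, 0.437 for monoamine genes, 0.729 for cell cycle genes and 0.459 for the fibroblast, unfolded protein, atrophy and erythroid lists, so none of these calls held. Single arrays ended calls: Saline-10D replicate 3 those of the neutrophil (0.0602), fibroblast (0.0837), monoamine (0.0813), unfolded protein (0.110), erythroid (0.0602) and cell cycle lists (0.0881), Saline-10D replicate 1 that of the unfolded protein list (0.0531), Saline-10D replicate 2 those of the atrophy (0.103), erythroid (0.0604) and cell cycle lists (0.208), and Saline-10D replicate 4 that of the atrophy list (0.0849). MDMA-10D replicate 1 did so for the atrophy (0.0753), erythroid (0.259) and cell cycle lists (0.600), replicate 2 for the atrophy (0.138), fibroblast (0.0600) and unfolded protein lists (0.114), and replicate 4 for the monoamine list (0.0735). The exact permutation p of the list means was 0.0286 for the clock activator and repressor lists, and 0.0571 to 0.229 for the 13 other lists called. Heat shock genes (adjusted p = 0.392) and immediate early genes (0.439) were not called.

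Some cardiac and DNA methylation genes lay apart within lists that were not called at 10 days. In the adrenergic and calcium handling list (adjusted p = 0.115) Slc8a1, the sodium-calcium exchanger (−1.004 ± 0.25), Adcy5, a cardiac adenylyl cyclase (−0.87 ± 0.26), and Adra1b, an adrenergic receptor (−0.73 ± 0.22), fell adjusted over the list alone, and Grk2, a kinase that desensitises adrenergic receptors, rose (+0.61 ± 0.21). In the DNA methylation list (adjusted p = 0.392) Dnmt3a, a de novo methyltransferase, rose adjusted over the list alone (+0.71 ± 0.19), while Dnmt3b stood at +0.64 ± 0.26 and Tet3, a demethylating enzyme, at −0.48 ± 0.18. Myh7, the slow myosin of the fetal heart, was at +1.13 ± 0.35 in a list of hypertrophy genes that was not called (adjusted p = 0.937). Over all genes the adjusted p of these 8 genes was 0.185 to 0.219.

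In limma 0 of 26487 genes passed at 10 days, with a smallest adjusted p of 0.185. At an unadjusted p under 0.05 there were 4570 genes, 2288 higher and 2282 lower, where chance would give 1324 on average. Genes are not independent, so by chance such a count can lie far from its average. The same holds for the shares of genes without overlap given here and below. With array weights 3251 genes were called, and 718 genes (2.71%) had no overlap between the groups, where chance gives 2.86%. The genes with the smallest p that met the naming conditions were Wdcp (−1.30 ± 0.23), Lpcat3, which remodels membrane phospholipids (−0.92 ± 0.17), Cep83os (−1.54 ± 0.30), Fam102a (+0.80 ± 0.17) and Stmn2, a neuronal regulator of microtubules (+1.12 ± 0.24). The count rested on 1 array: without Saline-10D replicate 2, 3470 genes were called, 1909 higher and 1561 lower, and without MDMA-10D replicate 1 there were 5. In the fit without Saline-10D replicate 2, singled out after the values were seen, Arntl (−1.95 ± 0.34, adjusted p = 0.00367), Npas2 (−1.27 ± 0.28, 0.00858), Per3 (+1.82 ± 0.31, 0.00333), Ciart (+1.39 ± 0.24, 0.00333), Cry2 (+2.01 ± 0.42, 0.00653) and Dbp (+0.89 ± 0.24, 0.0249) passed. Over all alternatives the adjusted p of Arntl in this comparison ranged from 0.00367 to 0.702.

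After 35 days of MDMA, Arntl was the most strongly lowered clock gene, and it passed over all genes. It fell by 2.23 ± 0.32 on the log2 scale (adjusted p = 0.0407), a 4.70-fold lower level with a 95% interval of 2.94 to 7.49, from 11.47 ± 0.34 (SD, n = 4) in Saline-35D to 9.24 ± 0.52 in MDMA-35D, and all 4 MDMA arrays lay below all 4 saline arrays. In the files the gene lies on chromosome 7 at 120424163 to 120457636 of MM9, and both of its features were lower, by −2.04 and −2.43. Npas2 was at −0.91 ± 0.26 (adjusted p = 0.200) and Clock, the dimer partner of BMAL1, at −0.64 ± 0.18 (adjusted p = 0.200; its 4 features from −1.14 to −0.15). Adjusted over the list alone, Arntl, Npas2 and Clock fell, and over all genes Arntl alone.

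The activator list was lower in all 6 members (mean −0.77, camera adjusted p = 5.71e-05, fry adjusted p = 0.00120), with adjusted p = 0.0613 with an estimated correlation. Its mean was 10.9 ± 0.202 (SD, n = 4) in MDMA-35D and 11.7 ± 0.114 in Saline-35D (exact permutation p = 0.0286). Of its members that encode repressors, Cry1 stood at −0.29 ± 0.18 and Nfil3 at −0.18 ± 0.17. On the repressor and output side the list was not called (8 of 11 higher, mean +0.27, adjusted p = 0.155), and Ciart (+0.81 ± 0.24) and Dbp (+0.72 ± 0.22) rose adjusted over the list alone. Per3 stood at +0.67 ± 0.30, Cry2 at +0.53 ± 0.48, Per1 at +0.49 ± 0.27, Per2 at +0.26 ± 0.33, Nr1d1 at −0.10 ± 0.16, Nr1d2 at −0.52 ± 0.26, Bhlhe40 at +0.06 ± 0.13, Tef at −0.04 ± 0.19 and Hlf at +0.09 ± 0.29. Cirbp and Rbm3 differed by +0.26 ± 0.13 and +0.01 ± 0.19. The clock output list of heart was at a mean of −0.14 in these arrays.

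Cell cycle genes were higher in all 15 members in MDMA-35D (mean +0.88, adjusted p = 5.71e-05), with Birc5, a mitotic survivin, at +1.53 ± 0.56, Mcm5, a replicative helicase subunit, at +1.17 ± 0.38, and Mki67 at +1.08 ± 0.43. The list mean was 9.82 and 10.2 in MDMA-35D replicates 1 and 3 and 8.05 and 7.52 in replicates 2 and 4, against 7.81 to 8.27 in Saline-35D (exact permutation p = 0.371), with adjusted p = 0.785 with an estimated correlation. Matrix and fibrosis genes were higher in 18 of 19 cases (mean +0.53, adjusted p = 0.00640), such as Timp1, an inhibitor of matrix proteases (+1.53 ± 0.52), Col8a1 (+1.12 ± 0.39) and Spp1, osteopontin (+2.60 ± 1.15), and macrophage markers in 9 of 12 (mean +0.32, adjusted p = 0.00656). In the macrophage list Fcer1g (+0.90 ± 0.28) and Tyrobp (+0.74 ± 0.24), partners of immune receptors, rose adjusted over the list alone. With an estimated correlation the adjusted p was 0.794 for the matrix list and 0.785 for the macrophage list. Both lists took their highest array means in MDMA-35D replicate 3 (12.4 and 12.6; exact permutation p = 0.314 each), and without it both calls were lost (adjusted p = 0.227 and 0.195). The matrix call was also lost without MDMA-35D replicate 1 (0.0638) and without Saline-35D replicate 1 (0.0790).

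Fatty acid oxidation genes were lower in 21 of 24 cases in MDMA-35D (mean −0.18, adjusted p = 0.00504), and ribosomal protein genes higher in 40 of 42 (mean +0.12, adjusted p = 4.94e-04; Rps15 +0.26 ± 0.11). Both had adjusted p = 0.785 with an estimated correlation. The exact permutation p was 0.0571 and 0.114. Acot1, a cytosolic acyl-CoA thioesterase, fell adjusted over the list alone (−0.89 ± 0.18), and Ppara, the receptor that drives this program, was at −0.44 ± 0.17. The atrial and epicardial markers were not called in this comparison (adjusted p = 0.784 and 0.745), nor were brown adipocyte (0.328), heat shock (0.156), hypertrophy (0.187; Myh7 +0.69 ± 0.35), adrenergic and calcium handling (0.745), immediate early (0.893) and DNA methylation genes (0.342; Uhrf1, a guide of maintenance methylation in dividing cells, +1.28 ± 0.50).

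At 35 days 3 genes were called, 2 higher and 1 lower, beside 3421 at an unadjusted p under 0.05. After quantile normalisation 1 was higher and 1 lower, and with each array centred on its median 1 was higher and 0 lower. The 2 that rose were predicted genes chosen after their values were seen, Gm3834 (+1.03 ± 0.15, adjusted p = 0.0407) and Gm10526 (+1.39 ± 0.22, adjusted p = 0.0448). Next by p among the named genes came Il27, a cytokine subunit (+1.36 ± 0.24, adjusted p = 0.101), Zfp74 (−0.68 ± 0.14), Banp (−0.73 ± 0.16), Rpl13-ps3 (+0.87 ± 0.20), Sprr2i (+1.67 ± 0.39) and Pak6 (+0.66 ± 0.16), none of which passed. Groups did not overlap in 2045 genes (7.72%, where chance gives 2.86%). Leaving out single arrays took the count from 0 (without Saline-35D replicate 1, 2 or 4, or MDMA-35D replicate 1 or 3) to 77 (without Saline-35D replicate 3), with 1 without MDMA-35D replicate 2 and 6 without replicate 4. Arntl kept changes of −2.53 to −2.04 over all alternatives, at adjusted p of 0.00171 to 0.403, and lost its call without Saline-35D replicates 1, 2 or 4 (0.146, 0.160, 0.0592) and without MDMA-35D replicates 1 or 3 (0.159, 0.178).

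The third comparison asked what remained 25 days after MDMA had been stopped. Arntl in MDMA-10/25D (11.76 ± 0.46, SD, n = 4) was within the saline spread (+0.28 ± 0.32, adjusted p = 0.936), as were Npas2 (+0.27 ± 0.26), Clock (−0.04 ± 0.18), Per3 (−0.42 ± 0.30), Cry2 (−0.31 ± 0.48), Ciart (−0.07 ± 0.24) and Dbp (−0.27 ± 0.22). The 95% interval of the Arntl change, −0.39 to +0.96, did not reach the −1.79 and −2.23 measured under MDMA. The activator and repressor lists had adjusted p of 0.799 and 0.369. The clock genes Cry1, Nfil3, Per1, Per2, Nr1d1, Nr1d2, Bhlhe40, Tef and Hlf, and the cold-inducible Cirbp and Rbm3, had adjusted p of 0.816 or more, and the largest change among them was that of Per2 (−0.37 ± 0.33).

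In MDMA-10/25D 264 genes were called, 260 that rose and 4 that fell, beside 2201 at an unadjusted p under 0.05. The count depended on the model: 1 gene was called with only the arrays compared, 11 with 1 test per feature and 0 with a replicate block. With alternatives added after the data were seen, it was 1 with the atrial and 4 with the brown adipocyte list mean as a covariate, and 0 without the arrays of deviating atrial signal. Of the 260, 134 (51.5%) were pseudogenes and 47 protein coding, while pseudogenes made up 4.02% of the genes tested (Fisher's exact p = 2.17e-116). That p counts genes as independent, which they are not, so it does not measure the spread between arrays. Among the named genes Ces1f, a liver-type carboxylesterase (+2.33 ± 0.41), H2-Q10, a class I histocompatibility gene (+1.95 ± 0.35), G6pd2, a retrogene of glucose-6-phosphate dehydrogenase (+2.06 ± 0.41), Fabp5l2 (+1.90 ± 0.41) and the ribosomal pseudogenes Rpl30-ps6 (+2.17 ± 0.49), Rps24-ps2 (+2.15 ± 0.43), Rpl7a-ps12 (+2.04 ± 0.41) and Rpsa-ps11 (+1.87 ± 0.38) rose, at adjusted p of 0.0391 to 0.0428, each without overlap between groups. Gm3834 and Gm10526, named after their values were seen, rose here too (adjusted p = 0.0391 and 0.0360). All these calls were borderline: each held in 10 or 11 of 22 alternatives (for H2-Q10 in 11 of 23). Their largest adjusted p over the alternatives ran from 0.126 (Gm10526) to 0.223 (Fabp5l2 and Rpl30-ps6).

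**Figure D3:**
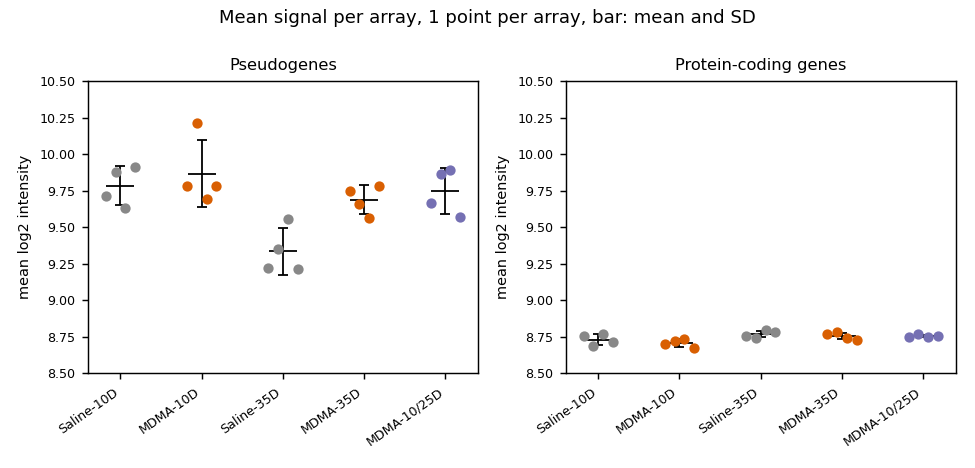
Mean log2 intensity (vertical axes, drawn from 8.5) of all 1066 pseudogenes and of 18674 protein-coding genes in the 5 groups (horizontal axes), with 1 point per array and bars for the mean and SD of 4 arrays. Pseudogenes averaged 9.33 in Saline-35D and 9.69 to 9.87 in the other groups.

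The mean log2 signal of all pseudogenes was 9.33 ± 0.160 (SD, n = 4) in Saline-35D, 9.69 ± 0.0989 in MDMA-35D, 9.75 ± 0.155 in MDMA-10/25D, 9.78 ± 0.131 in Saline-10D and 9.87 ± 0.232 in MDMA-10D. Their median change against Saline-35D was +0.27 in MDMA-35D and +0.25 in MDMA-10/25D, while that of protein-coding genes was −0.03 and −0.06. With pseudogenes left out, an alternative added after the data were seen, 4 genes were called in MDMA-10/25D. The count of 264 became 0 without Saline-35D replicate 1 or 4 or MDMA-10/25D replicate 1, 2 or 3, 5 without Saline-35D replicate 2, and 447 without Saline-35D replicate 3.

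Marker lists of other cell types were higher in MDMA-10/25D. Nerve markers were higher in 9 of 9 cases (mean +0.68, adjusted p = 0.00102), and Th, the rate-limiting enzyme of catecholamine synthesis, rose over all genes (+1.85 ± 0.43, adjusted p = 0.0491), while Prph, a peripheral neurofilament, was at +0.99 ± 0.35. The call of Th was borderline too: it held in 9 of 22 alternatives, at adjusted p of 0.0367 to 0.273 over all of them. Erythroid markers were higher in 9 of 10 cases (mean +0.35, adjusted p = 8.73e-04; Hba-a2 +0.26 ± 0.11), lymphocyte markers in 13 of 14 (mean +0.48, adjusted p = 0.00102; Ighm +1.40 ± 0.46) and adipocyte markers in 8 of 10 (mean +0.78, adjusted p = 0.0112; Retn +1.74 ± 0.57, Adipoq +1.41 ± 0.79). All 4 lists had adjusted p = 0.945 with an estimated correlation, and exact permutation p of 0.0286 for nerve and adipocyte, 0.0857 for erythroid and 0.2 for lymphocyte markers. Adjusted over the list alone, Th rose in the nerve list and 2 members in the lymphocyte list. Atrial and brown adipocyte markers had adjusted p of 0.0732 each. The erythroid call was lost without Saline-35D replicate 4 (0.0588), the adipocyte call without Saline-35D replicate 4 (0.0505) or MDMA-10/25D replicate 1 (0.172), and the lymphocyte call without MDMA-10/25D replicate 2 (0.107).

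Both MDMA groups of the 35-day arm were then set against each other, which tests continued against stopped exposure. The saline arrays do not enter these mean differences, but all 20 arrays enter the spread behind the p-values. Arntl fell by 2.52 ± 0.32 in MDMA-35D relative to MDMA-10/25D (adjusted p = 0.00857, a 5.72-fold lower level), with no overlap between the arrays. With only the arrays compared, the adjusted p of Arntl was 0.544. Npas2 stood at −1.18 ± 0.26, Clock at −0.61 ± 0.18, Dbp at +0.997 ± 0.22, Ciart at +0.88 ± 0.24 and Per3 at +1.09 ± 0.30, and each of these changed adjusted over its list alone. The activator list was lower in all 6 members (mean −0.83, adjusted p = 2.85e-07) and kept its call with an estimated correlation (adjusted p = 0.0151), the only list call to do so in any comparison. The repressor list was higher in 8 of 11 members (mean +0.44, adjusted p = 9.19e-04), with adjusted p = 0.277 with an estimated correlation and exact permutation p = 0.0571.

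Besides Arntl, 3 genes were called between these groups: Ces1f fell by 2.89 ± 0.41 (adjusted p = 0.0205), Vnn3, a pantetheinase, fell by 1.82 ± 0.28 (adjusted p = 0.0406), and the predicted gene Gm4495 rose (+1.12 ± 0.18, adjusted p = 0.0444). After cyclic loess 0 were higher and 3 lower. Vnn3 and Gm4495 were chosen after their values were seen. Tmem45b (−2.997 ± 0.64), Ncapd2, a condensin subunit (+0.60 ± 0.15), Olfml3 (+0.79 ± 0.20) and Dpep2 (+1.52 ± 0.39) had the next smallest p among named genes and did not pass. There were 1777 genes at an unadjusted p under 0.05, and 1028 (3.88%) without overlap, where chance gives 2.86%. Leaving out MDMA-35D replicate 1 or 3 or MDMA-10/25D replicate 1 or 4 left 0 genes called, leaving out MDMA-35D replicate 4 or MDMA-10/25D replicate 3 left 1, and leaving out MDMA-10/25D replicate 2 left 2. The adjusted p of Arntl without MDMA-35D replicate 1 or 3 or MDMA-10/25D replicate 1 or 4 was 0.0593, 0.0647, 0.0690 and 0.0506, and ranged from 4.45e-04 to 0.614 over all alternatives.

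Fat markers were lower in MDMA-35D than in MDMA-10/25D as lists, with overlap between the arrays in their means. Adipocyte markers were lower in 9 of 10 cases in MDMA-35D (mean −1.03, adjusted p = 1.57e-05), with Adipoq, adiponectin, at −2.18 ± 0.79 and Retn at −1.55 ± 0.57. Brown adipocyte markers were lower in 7 of 8 (mean −1.19, adjusted p = 4.61e-04), with Dio2 at −2.47 ± 0.57, Adrb3 at −2.33 ± 0.56 and Ucp1 at −2.18 ± 1.09. Both lists had adjusted p = 0.277 with an estimated correlation and an exact permutation p = 0.0857, and 5 and 3 of their members fell adjusted over the list alone. Lymphocyte markers (12 of 14 lower, adjusted p = 1.56e-04; Cd79a −1.19 ± 0.37) and erythroid markers (10 of 10 lower, adjusted p = 3.78e-04; Alas2 −0.60 ± 0.19) were lower too, with adjusted p of 0.384 and 0.339 with an estimated correlation and exact permutation p of 0.114 and 0.0571.

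Genes that write, read or erase DNA methylation were higher in 14 of 17 cases in MDMA-35D than in MDMA-10/25D (mean +0.26, adjusted p = 0.00461, exact permutation p = 0.0286), with adjusted p = 0.277 with an estimated correlation. Against Saline-35D the list was not called in either group: it was lower in 14 of 17 cases in MDMA-10/25D (mean −0.14, adjusted p = 0.266, exact permutation p = 0.0286) and higher in 12 of 17 in MDMA-35D (mean +0.12, adjusted p = 0.342, exact permutation p = 0.0857). Uhrf1 was at +1.71 ± 0.50, and Mbd2, a reader of methylated DNA, at +0.45 ± 0.23. Beside it, cell cycle genes were higher in all 15 members (mean +1.05, adjusted p = 4.76e-09, and adjusted p = 0.339 with an estimated correlation; Mcm5 +1.19 ± 0.38, Mki67 +1.34 ± 0.43). Their array means again differed within MDMA-35D (exact permutation p = 0.257). Adjusted over the list alone, 0 methylation genes and 2 cell cycle genes rose.

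Oxidative genes were lower in the same comparison: fatty acid oxidation in 22 of 24 cases (adjusted p = 0.00160; Angptl4, a target of fatty acid receptors, −0.91 ± 0.29) and oxidative phosphorylation in 41 of 46 (adjusted p = 0.0156; Cox6a2 −0.15 ± 0.09). Macrophage (10 of 12; Fcer1g +0.70 ± 0.28; 0.00271), matrix (17 of 19; Col8a1 +1.28 ± 0.39; 0.00646) and ribosomal protein genes (33 of 42; Rpl37 +0.43 ± 0.18; 0.0159) were higher, and unfolded protein (10 of 14; Dnajb9 −0.35 ± 0.15), monoamine (12 of 15; Slc6a4, the serotonin transporter that MDMA acts on, −1.27 ± 0.46) and epicardial genes (6 of 7; Upk3b −2.49 ± 1.36) lower, each at adjusted p = 0.0279. With an estimated correlation the adjusted p was 0.402 for fatty acid oxidation, 0.576 for oxidative phosphorylation, 0.461 for macrophage, 0.608 for matrix, 0.614 for ribosomal, 0.452 for unfolded protein, 0.393 for monoamine and 0.576 for epicardial genes. With the mean of the brown adipocyte markers as a covariate, added after the data were seen, 5 lists were called in this comparison instead of 16, and the macrophage and matrix lists were lower in MDMA-35D and not called (means −0.0428 and −0.24). The exact permutation p of the 8 lists was 0.0571 to 0.371. Without MDMA-35D replicate 3 the calls of the oxidative phosphorylation (0.130), macrophage (0.186), matrix (0.356), ribosomal (0.249), unfolded protein (0.12), monoamine (0.0712) and epicardial lists (0.183) were lost. MDMA-35D replicate 4 ended those of the unfolded protein (0.191), monoamine (0.129) and epicardial lists (0.191), and MDMA-35D replicate 1 that of the matrix list (0.116). MDMA-10/25D replicate 1 ended that of the unfolded protein list (0.0657), replicate 2 those of the monoamine (0.0591) and oxidative phosphorylation lists (0.0519), replicate 3 those of the matrix (0.0641) and unfolded protein lists (0.0504), and replicate 4 those of the unfolded protein (0.0520) and epicardial lists (0.0854).

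The last comparison asked whether the effect of MDMA differed between 35 and 10 days. For Arntl the difference was −0.44 ± 0.45 (adjusted p = 0.767) and for Per3 −0.96 ± 0.42 (adjusted p = 0.579), both chosen outside the naming rule. In limma 0 genes passed, with a smallest adjusted p of 0.568, beside 2268 at an unadjusted p under 0.05 and 1576 with array weights; without Saline-10D replicate 2 there were 21. The smallest p among named genes belonged to Prdm15 (−0.99 ± 0.20), Banp (−1.07 ± 0.22), Zxda (−1.07 ± 0.26) and Pdgfd (−1.11 ± 0.27) on the lower side, and to Aqp4, a water channel (+1.70 ± 0.38), C1rl (+1.52 ± 0.34), Chgb, a secretory granule protein (+1.21 ± 0.28), and Cbx3-ps4 (+1.43 ± 0.40) on the higher side.

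Matrix genes were more positive at 35 than at 10 days in 18 of 19 cases (mean difference +0.58, adjusted p = 0.00661), among them Ccn2, connective tissue growth factor (+0.71 ± 0.34), and Col1a1 (+0.48 ± 0.24). Atrial (8 of 9; Myl7 +4.86 ± 1.83; mean +1.86, adjusted p = 0.0160), epicardial (6 of 7; Upk1b +2.76 ± 1.23; mean +1.88, adjusted p = 0.0160) and nerve markers (8 of 9; Tubb3 +1.51 ± 0.64, Th +1.39 ± 0.61; mean +0.77, adjusted p = 0.0329) were more positive as well. All 4 lists had adjusted p = 0.843 with an estimated correlation, and 0 members passed adjusted over the list alone. The clock activator and repressor lists did not differ by this test (adjusted p = 0.351 and 0.357). Without Saline-10D replicate 3 all 4 calls were lost (adjusted p = 0.0572 for matrix, 0.240 for atrial, 0.214 for epicardial and 0.240 for nerve genes), as they were without Saline-35D replicate 1 (0.0845, 0.197, 0.0845 and 0.0845). The matrix call was lost without MDMA-35D replicate 3 (0.151), the other calls without MDMA-35D replicate 2 (0.0524 each), and the nerve call also without MDMA-10D replicates 2 and 4 and MDMA-35D replicate 1 (0.0545, 0.0980 and 0.0858).

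Across all 26487 genes, which are not independent replicates, the MDMA changes at 10 and at 35 days, which share no arrays, had Pearson's r = 0.312 and Spearman's rho = 0.297, with a covariance of 0.0534. This r was 0.111 without MDMA-35D replicate 4, to 0.195 without MDMA-10D replicate 2, and 0.438 without MDMA-35D replicate 2. The changes at 10 days and in MDMA-10/25D had r = −0.148, from −0.255 without MDMA-10/25D replicate 3 to −0.0373 without replicate 4. The changes in MDMA-35D and MDMA-10/25D had r = 0.546 and the same sign in 69.8% of genes, but they share the Saline-35D arrays: unchanged groups simulated against those arrays gave r = 0.501 and 66.7%. The covariance was 0.0703 against a simulated 0.0443, a difference of 0.0261, and with the saline arrays split between the comparisons r was 0.0977, 0.299 and 0.282. Without MDMA-10/25D replicate 3 or MDMA-35D replicate 2 it was 0.422 and 0.426. Gm3834 and Gm10526 rose in both, and the shared arrays enter both of these calls.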

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

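The tests of a single wrong label and of a lack of atrial tissue in Saline-10D replicate 2, and the margin for reading the first, were chosen only after its values had been seen. Gene levels were checked for arrays far from the other 3 of their group, with a test that by chance singles out about 1 set in 20. Of 337 sets of 4 arrays, over 119 genes, 22 stood out, where 16.8 would by chance, 4 of them in Saline-10D replicate 2 and 4 in Saline-35D replicate 1. Log2 levels follow, with the range of the other 3 arrays in brackets.

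Saline-10D replicate 2 stood apart in Bpgm at 9.83 (8.77 to 8.80), Hyou1 at 10.03 (10.97 to 11.11), Prdm15 at 9.66 (9.17 to 9.21) and Rps13 at 12.61 (11.51 to 11.54). Saline-35D replicate 1 stood apart in Bhlhe40 at 13.46 (13.79 to 13.86), Fcer1g at 10.6 (10.80 to 10.83), Myl7 at 12.44 (14.63 to 14.82) and Timp1 at 10.78 (11.65 to 11.72). In Saline-10D replicate 3 Bhlhe40 was at 14.01 (13.48 to 13.56) and Nr1d1 at 14.37 (14.04 to 14.09), and in replicate 1 Th was at 7.02 (6.31 to 6.40). In Saline-35D, Nr1d2 was at 11.02 in replicate 4 (11.63 to 11.73) and Zfp74 at 8.15 in replicate 2 (8.11 in the others). MDMA-10/25D replicate 3 stood apart in Arntl at 11.07 (11.91 to 12.04), Gm3834 at 6.51 (6.25 to 6.30) and Per3 at 8.44 (7.74 to 7.84), replicate 2 in Cd79a at 7.51 (5.28 to 5.56) and replicate 4 in Cox6a2 at 14.32 (14.49 to 14.52). In MDMA-10D, Myl7 was at 5.55 in replicate 1 (6.42 to 6.50), Ulk1 at 11.39 in replicate 2 (12.36 to 12.38) and Aqp4 at 6.82 in replicate 4 (6.24 to 6.27). In MDMA-35D, Rbm3 was at 11.93 in replicate 3 (11.55 to 11.60).

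A test of the difference between the MDMA effects at 35 and 10 days called 4 lists, a number for which chance cannot be excluded (86 of 100 splits gave as many): matrix and fibrosis genes (mean log2 difference 0.579, adjusted p = 0.00661), epicardial markers (1.88, 0.0160), atrial markers (1.86, 0.0160) and nerve markers (0.767, 0.0329), each with adjusted p = 0.843 with an estimated correlation. All 4 calls were lost without Saline-10D replicate 3 (0.0572, 0.214, 0.240 and 0.240) and without Saline-35D replicate 1 (0.0845, 0.0845, 0.197 and 0.0845), and 0 lists were called with the atrial covariate or without the arrays of deviating atrial signal, both added after the data had been seen.

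Saline-10D replicate 2 lay among the MDMA-10D arrays over many genes: with the mean of the other saline arrays at 0 and the MDMA-10D mean at 1, its median place on the 3470 genes called without it was 1.06, against −0.168 to 0.229 for the other saline arrays and 0.71 to 1.2 for the MDMA-10D arrays. Those genes, and the 6 clock genes below, were called between these other arrays, whose ranges therefore lie apart by construction. Only the place of Saline-10D replicate 2 is free of that choice. The tables argue against a lack of atrial tissue as the reason, since Saline-10D replicate 4, which also lacked atrial signal, lay at −0.135 on 1065 genes called without both arrays. A single wrong label may be the reason and stays open: over 6 clock genes the array lay at 0.371, below the lowest MDMA-10D array (0.549) by less than the SD of those arrays (0.331). A swap of labels with MDMA-10D replicate 1 stays open too, since on 4283 genes called without both Saline-10D replicate 2 lay at 0.93 and that array at 0.533, close to the midpoint for an SD of 0.13 among the other MDMA-10D arrays, and with both exchanged 4201 genes were called where the groups as given had 0. With array weights, however, the other split with most calls (5973) exchanged Saline-10D replicate 2 with MDMA-10D replicate 2, so the counts do not single out a partner. No biological explanation was tested, and Saline-10D replicate 2 was kept in its group.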

How the results depend on the processing

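Covariates for sex signal, atrial and brown adipocyte list means, leaving out arrays of deviating atrial signal (Saline-10D replicates 1 and 3, Saline-35D replicate 1, MDMA-35D replicate 3) and leaving out pseudogenes were chosen only after the data had been seen, and unless stated the cause of a change was not tested. Over all alternatives 0 of the called named genes reversed. Of the values of all named genes under each alternative, called or not, 1214 of 1342 kept their direction and their side of the threshold at 10 days, 854 of 953 at 35 days, 658 of 829 in MDMA-10/25D, 675 of 761 between the MDMA groups of the 35-day arm and 481 of 507 for the difference. At 10 days and for the difference 0 genes were called, so no call could be lost there. Calls were lost in 36 values at 35 days, 128 in MDMA-10/25D and 46 between the MDMA groups. Arntl kept its direction at 10 days (−2.13 to −1.57), at 35 days (−2.53 to −2.04) and between the MDMA groups (−2.79 to −2.33). Other normalisations called 2, 3 and 1 genes at 35 days (quantile, cyclic loess, each array centred on its median), 285, 351 and 334 in MDMA-10/25D, and 0 at 10 days and for the difference. Array weights called 3251 genes at 10 days, 2803 at 35 days, 781 in MDMA-10/25D, 179 between the MDMA groups and 1576 for the difference; an unadjusted p under 0.05 with at least a 1.5-fold change, by construction a looser threshold, gave 2797, 1797, 1296, 858 and 1860. At 35 days 1 gene was called without the dim features and 1 with a trend and robust variance model, 0 with only the arrays of the groups compared, with odd or even array position, with the atrial covariate and without the deviating arrays, and 5 with the sex signal. In MDMA-10/25D 11 were called with 1 test per feature, 1 with only the arrays compared, 1 with the atrial and 4 with the brown adipocyte covariate, 0 without the deviating arrays and 4 without pseudogenes. Between the MDMA groups 1 was called without the dim features, 2 with odd or even position, 2 with the sex signal, and 0 with only the arrays compared, with the brown adipocyte covariate and without the deviating arrays. Fewer arrays give fewer degrees of freedom where only those compared were used. Leaving out 1 array at a time gave 0 to 3470 genes at 10 days (5 without MDMA-10D replicate 1, 3470 without Saline-10D replicate 2), 0 to 77 at 35 days (77 without Saline-35D replicate 3), 0 to 447 in MDMA-10/25D (447 without Saline-35D replicate 3), 0 to 3 between the MDMA groups (2 without MDMA-10/25D replicate 2) and 0 to 21 for the difference (21 without Saline-10D replicate 2). Lists called with an estimated correlation numbered 0 at 10 days, 0 at 35 days, 0 in MDMA-10/25D, 1 between the MDMA groups and 0 for the difference, and with fry 0, 1, 0, 1 and 0. At 10 days 9 lists were called without the dim features and 9 with the atrial covariate; at 35 days 3 without the deviating arrays; in MDMA-10/25D 7 with only the arrays compared and 9 with the trend and robust model; between the MDMA groups 5 with the brown adipocyte covariate; for the difference 7 after cyclic loess and 0 with the atrial covariate or without the deviating arrays. With the brown adipocyte covariate 2 lists that were higher in MDMA-35D than in MDMA-10/25D reversed, macrophage markers to a mean of −0.0428 and matrix genes to −0.24. Leaving out 1 array gave 8 to 17 lists at 10 days (8 without Saline-10D replicate 3), 5 to 9 at 35 days, 2 to 7 in MDMA-10/25D (without Saline-35D replicates 4 and 3), 10 to 18 between the MDMA groups (10 without MDMA-35D replicate 3) and 0 to 8 for the difference (0 without Saline-10D replicate 3 or Saline-35D replicate 1, 8 without MDMA-35D replicate 4). Correlations of effects ranged over arrays left out from 0.111 to 0.438 (10 and 35 days), −0.255 to −0.0373 (10 days and MDMA-10/25D) and 0.422 to 0.629 (MDMA-35D and MDMA-10/25D), and the last was 0.0977, 0.299 and 0.282 with the saline arrays split, which ended the sharing of arrays and also left 2 saline arrays in each comparison, so the cause of the lower r was not separated. The labels do not say whether replicate numbers pair the arrays. Same-number correlations ran from −0.239 to 0.233, and at 10 days all were positive (0.0195 to 0.233). An array was closest to its own number in 2, 2, 0 and 0 of 4 cases, so pairing was neither shown nor excluded. With the numbers as a replicate block 0 genes were called at 10 days, 2 at 35 days, 0 in MDMA-10/25D, 1 between the MDMA groups and 0 for the difference, and 15, 6, 4, 17 and 4 lists. Signal over background limits the dim genes, whose levels come near the random-probe control of 18.2 to 26.4, and 4 arrays per group limit the calls of smaller changes. Among genes simulated with independent noise and a log2 change of 1, 50% were called at 10 days and 54% at 35 days. For a log2 change of 2 these shares were 96% and 90%.

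Some genes that were not called changed sign, with 70 values of 19 results, so their direction was not settled. The mean changes with the other sign follow. After cyclic loess in MDMA-10/25D they were Clock 0.0184 and Cry1 0.0195. With each array centred they were at 10 days Nfil3 −0.0136, and in MDMA-10/25D Cry1 0.0109, Nfil3 0.0102, Nr1d1 0.0301 and Per1 0.00813. With array weights they were at 10 days Nfil3 −0.0609, and at 35 days Nr1d1 0.00659 and Rbm3 −0.0786, and in MDMA-10/25D Nfil3 0.0584, Nr1d1 0.0797, Per1 0.0232 and Rbm3 −0.0171. With the atrial covariate they were at 10 days Hlf 0.0137 and Nfil3 −0.0847, and in MDMA-10/25D Clock 0.00229 and Nfil3 0.0151. With the brown adipocyte covariate they were at 10 days Cry1 0.0378, and at 35 days Rbm3 −0.00903 and Tef 0.0238, and in MDMA-10/25D Per1 0.157, and between the MDMA groups Ucp1 1.05. Without the deviating arrays they were at 10 days Nfil3 −0.0559, and at 35 days Bhlhe40 −0.00281, Rbm3 −0.166 and Tef 0.191, and in MDMA-10/25D Cry1 0.0469 and Rbm3 −0.0714. Without the dim features they were at 10 days Rbm3 −0.0218, and between the MDMA groups Mbd2 −0.0057. Over arrays left out these genes ranged at 10 days Cry1 −0.127 to 0.0726, Nfil3 −0.0406 to 0.0672 and Rbm3 −0.0492 to 0.233, and at 35 days Bhlhe40 −0.0316 to 0.118, Hlf −0.102 to 0.287, Nr1d1 −0.171 to 0.00468, Rbm3 −0.082 to 0.0646 and Tef −0.156 to 0.109, and in MDMA-10/25D Ciart −0.267 to 0.101, Cirbp −0.0201 to 0.186, Clock −0.143 to 0.105, Cry1 −0.118 to 0.0962, Nfil3 −0.159 to 0.0773, Nr1d1 −0.0677 to 0.0494, Per1 −0.253 to 0.21 and Rbm3 −0.0875 to 0.0723. Ucp1 is a member of the brown adipocyte list, so its value under that covariate was affected by construction. The clock activator list, not called in MDMA-10/25D, had a mean of −0.0241 with the brown adipocyte covariate.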

Other observations

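The tests of clock genes below were all chosen only after the results had been seen, as were those of genomic DNA, of array position and of bright parent genes for the pseudogenes, and the reason given for setting aside the test of dimmer parent genes.

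The clock activator list, which also holds the repressors Cry1 and Nfil3, was lower in the MDMA-35D arrays, by a mean log2 change of −0.768. Arntl was 4.70-fold lower. The tables argue against atrial and brown fat tissue as the whole cause: with both as covariates the mean was −0.737 and Arntl stood at −2.20 ± 0.344, its adjusted p of 0.0917 going with a larger SE (0.32 before). They also argue against deviating Saline-35D arrays, since the list was lower against MDMA-10/25D too (adjusted p = 2.85e-07). In that comparison the Saline-35D arrays enter only the shared spread. The list kept its call there in all 25 alternatives, including that with only the arrays compared (camera or fry adjusted p up to 0.0151). A different clock time of dissection stays open, since the labels of 0 samples give an hour. An effect of MDMA on the clock genes may be the reason as well, and it cannot be told apart from the hour of dissection.

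Pseudogene signal was lower in the Saline-35D arrays (9.33 against 9.69 to 9.87 in the other groups). The tables argue against atrial and brown fat tissue as the whole cause (a median change in MDMA-10/25D of 0.262 with tissue covariates and 0.249 without). More parent messenger RNA read by the pseudogene probes stays open: for 76 bright parent genes the medians were 0.0379 for the parents and 0.288 for the pseudogenes, where bright probes may answer to a rise with less signal, and for 52 dimmer ones −0.0563 and 0.0769. The dimmer ones met the bound set before against this explanation (parents under 0.5 times the rise of their pseudogenes, permutation p = 0.00302), but that bound was wrong in not asking their pseudogenes to show the pattern, and these rose by 0.0769 where all pseudogenes rose by 0.249. Genomic DNA in the cDNA stays open, with −0.0246 in MDMA-10/25D and 0.0892 in MDMA-35D over 920 olfactory and vomeronasal receptor genes whose median log2 level of 4.57 lay within the random-probe control (4.18 to 4.72), as does array position, since 0 blocks of 4 positions on that slide held more than 1 group, and other tissues and biological explanations were not tested.

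Other splits of the same arrays into groups of the same sizes were counted. For gene counts 1 of 35 is the smallest share these splits allow. Only the real split reached its count at 35 days (3 called, highest of the other splits 0, 1 of 35). The same held in MDMA-10/25D (264, highest other 4, 1 of 35) and between the MDMA groups of the 35-day arm (4, highest other 1, 1 of 35). That share lies under 0.05, but it was not adjusted over these comparisons, which share arrays. Each of these counts also fell to 0 without single arrays, at 35 days without any 1 of 5 of the 8. Chance is therefore not excluded for any of them. With 0 genes called at 10 days (highest other 4201) and for the difference (highest other 43), all 35 and all 100 splits reach the real count by construction, so the count says nothing about chance there. The split with 4201 calls exchanged Saline-10D replicate 2 and MDMA-10D replicate 1. It was the highest of 35 splits, and a swap of these labels stays open. The count therefore does not tell a wrong label from a structure of the samples other than their groups. Without Saline-10D replicate 2 the real split called 3470 genes and the highest other 3285 (1 of 35), but that array was left out after its values had been seen, so this says nothing about chance either. For numbers of lists chance cannot be excluded in any comparison: 15 and highest other 19 at 10 days (2 of 35), 6 and 11 at 35 days (24 of 35), 4 and 10 in MDMA-10/25D (16 of 35), 16 and 16 between the MDMA groups (2 of 35), and 4 and 15 for the difference (86 of 100). With array weights it cannot be excluded either: 3251 genes and highest other 5973 at 10 days (6 of 35), and 2803 and 2945 at 35 days (2 of 35). The split with 5973 calls exchanged Saline-10D replicate 2 with MDMA-10D replicate 2, not with replicate 1.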
